A study of Mus musculus with 64 samples.

How the data were processed

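RNA was sequenced from whole tissue, from sorted MEP and from sorted SMP (lineage-negative, Sca-negative, Kit-positive, CD34-positive, CD16/32-low cells) of bone marrow and spleen, 64 libraries from 18 mice in all. Per the submitters' processing notes, the authors used Bowtie2 2.2.0, RSEM, DESeq2 and the GRCm38 genome. The notes do not give the order of these steps. The authors deposited 1 table of normalised counts (26286 genes), whose values are a normalised signal per gene and library and not whole reads. They also deposited 1 table of regularised log2 values (25287 genes), made from the same libraries by the authors, and 25164 genes are in both tables. Of the normalised table's identifiers, 25607 were matched to symbols and coordinates of GENCODE release M21.

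States, ages and mouse identifiers were read from the sample labels before the data were examined, as were the comparisons, the tests, the gene lists, the naming rule and most alternatives. Of the 64 libraries 63 were assigned, and 1 whole spleen library of mouse 27265, whose labels contradict each other, entered no comparison between groups. Each population has 3 crisis, 3 young WT and 3 remission mice (2 remission mice in spleen MEP), and 2 older WT mice (1 in whole spleen and 1 in spleen SMP). Crisis mouse 2608 is replicate 1 of crisis in each of the 6 populations, 2629 is replicate 2 and 2953 is replicate 3. Mice serve several populations, so populations are not independent of each other.

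Libraries hold 33.6 to 107.62 M normalised counts (median 50.6 M), and 16413 to 19940 genes above 0. By population the medians are 63.49 M in whole bone marrow, 88.19 in whole spleen, 50.52 in bone marrow MEP, 48.02 in spleen MEP, 48.5 in bone marrow SMP and 50.05 in spleen SMP. The smallest steps between low values show how the deposited columns were built: 15 libraries have 1 step size (single-step libraries), 4 have 2, 34 have 3 and 11 have 4 or more, as sums of separately scaled runs would. From these steps the depth was estimated at 21.0 to 50.9 M reads at the lower and 27.2 to 78.0 M at the upper bound. Sampling noise is small at this depth: between replicate libraries the variance was 3.86 to 42.3 times sampling noise (median 9.29, 56 pairs), so spread between libraries, which holds mice, sorting and preparation alike, limits the precision. Mitochondrial transcripts made up 1.81 to 6.84% of a library (median 3.46).

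The planned test used the deposited normalised counts as they stand. After the data were seen, the columns of a population were found not to share a scale, and each was divided by its median ratio to the geometric mean of the population (log2 factors from -0.928 to 0.512). Results without this rescaling are given as an alternative. Rescaled counts were turned into log2(count + 1), genes with a mean of at least 10 were kept, and limma 3.58.1 in R 4.3.3 fitted 1 mean per group and population with a trend and robust empirical Bayes. Where a group holds 1 library, that library is assumed to vary like the others. Tests were two-sided, Benjamini-Hochberg adjusted over all genes of a comparison, with a threshold of 0.05. An exact test of 3 against 3 mice cannot give a p under 0.1, so single genes were tested with limma alone. The comparisons are crisis against young WT, remission against crisis and remission against older WT in each population (18 in all), and 3 differences of the crisis effect between spleen and bone marrow. For these differences the mouse was a random block (correlation 0.314 in whole tissue, 0.549 in MEP, 0.277 in SMP). Remission and crisis differ in age as well as in state.

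There are 25 gene lists, written from textbook knowledge: heme synthesis, globins, red cell membrane and late erythroid, erythroid transcription factors, iron uptake and handling, erythropoietin and STAT5 response, megakaryocyte and platelet, stem and early progenitor, primary granule and promyelocyte, mature neutrophil, monocyte and macrophage, B cell, T and NK cell, mast cell with basophil and eosinophil, stroma and endothelium, interferon response, G1/S, G2/M, p53 response, oxidative stress defence, ERK pathway feedback, Ras and Rap regulators, unfolded protein and integrated stress response, inflammatory and NF-kB response, and stress erythropoiesis signals. Mitochondrial transcripts and Eif2s3y served as quality measures. Lists were tested with camera of limma at a preset correlation of 0.01 and, as an alternative, with an estimated correlation. Fry of limma was run as well and passed 5 lists in whole bone marrow, 4 in whole spleen, 6 in bone marrow SMP and 7 in spleen SMP in crisis, and 0 in the other contrasts. Its p values shift with the order of the group columns in the design, which was fixed at alphabetical order with capitals first. In an earlier run with another order 1 list fewer passed in whole spleen. Counts of list members are given after adjustment over all genes and over the list alone. Genes named by rule are Rasa3 and the 5 highest and 5 lowest log2 changes among called genes with a mean of at least 50, no overlap between groups and a symbol that marks neither a predicted gene, a Rik clone nor a pseudogene. Up to 4 called members of a list were named, or 2 where none was called. Some genes that these rules name are not reported here.

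The test was tried on simulated data with 200 changed genes. At 2-, 4- and 8-fold it recovered 53.7, 80.6 and 93.9% of them in whole bone marrow in crisis, 5.97, 43.3 and 77.3% in whole spleen, 67.2, 80.6 and 90.9% in bone marrow MEP, 58.2, 92.5 and 97% in spleen MEP, 77.6, 92.5 and 98.5% in bone marrow SMP and 50.7, 77.6 and 86.4% in spleen SMP. Whole spleen remission against 1 WT library recovered 0% at 2-fold. A simulated list of 20 genes shifted by 0.5 was found at the preset correlation in each of the 18 contrasts, and with an estimated correlation in all but whole spleen in crisis (adjusted p = 0.0547), whole spleen remission against WT (0.136) and spleen SMP remission against WT (0.0793). Simulated genes vary independently, which real genes do not.

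Alternatives were a pseudocount of 5, no filter, the deposited regularised log2 values, trimmed mean of M values (TMM) factors (30% and 5% trimmed), all WT mice as the control, age as a covariate among the young mice, the difference of differences for remission, no animal block, and leaving out each library in turn. Chosen after the data were seen were no rescaling, single-step libraries as a covariate, crisis and young WT libraries alone in the fit, leaving out mice 2726 and 27265, and leaving out 2 MEP libraries of doubtful animal, whose Eif2s3y level stood apart from that of other libraries under the same identifier. A DESeq2 test was not run, because the deposited values could not be turned back into whole reads. The position of a library between young WT (0) and crisis (1) was computed over 200 genes per population. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.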

Results

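Gene expression was measured in 64 RNA-seq libraries from 18 mice, in whole tissue, megakaryocyte-erythroid progenitors (MEP) and SMP cells of bone marrow and spleen. SMP are lineage-negative, Sca-negative, Kit-positive, CD34-positive, CD16/32-low cells, a gate that leaves out Sca-positive cells. The scat mice carry a mutant allele of Rasa3, which encodes a GTPase-activating protein that switches off Ras and Rap1, and were sampled in anemic crisis or in partial remission. Crisis (18 libraries of 3 mice, 23 to 28 days old) was compared with wild-type (WT) mice of the same ages (18 libraries of 7 mice). Remission (17 libraries of 5 mice, 32 to 58 days old) was compared with crisis and with WT mice of those ages (10 libraries of 3 mice). In each population there are 3 crisis mice and 3 young WT mice. Values are mean ± SD of rescaled normalised counts, with log2 fold changes, their standard errors (SE) and adjusted p from limma. The expression of 2 mice aged 58 days, 2726 (recorded as remission) and 27265 (recorded as WT), lies nearer to the opposite state, so gene counts in remission are also given without them where a population holds them.

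In whole bone marrow in crisis, genes of the erythropoietin response were among the highest. Erfe, which encodes erythroferrone, the hormone through which erythroblasts release iron for hemoglobin, was 78.9-fold higher (log2 6.30, SE 1.39, adjusted p = 0.0348, 13059 ± 3943 against 160.2 ± 28.6, n = 3 and 3). Cish, a feedback inhibitor of erythropoietin receptor signalling, was 50.7-fold higher (log2 5.67, SE 1.05, adjusted p = 0.027, 11099 ± 5478 against 197 ± 38.2). Fgf23, a hormone that lowers blood phosphate, reached 216 ± 171 and Ankrd36 347 ± 442, while both are listed at 0 in the 3 WT libraries (adjusted p = 0.0213 and 0.0296). Igll1, part of the surrogate light chain of the pre-B-cell receptor, fell by 5.59 on the log2 scale (SE 1.41, adjusted p = 0.0452, 581 ± 965 against 4818 ± 1146). Homer2, a scaffold protein, was also named by rule (log2 5.20, adjusted p = 0.0274). The other genes named by rule were the adhesion gene Egfl6 (-5.69, 0.0392), Lgr5 (-5.41, 0.0421), Etnk2 (-5.01, 0.0421) and Wnt10a (-4.98, 0.0357). The size of these falls is uncertain, as crisis replicate 1 stands above the other 2 (Egfl6 210 against 2.18 and 2.06). Over the settings Egfl6 ran from -7.72 to -4.66, Lgr5 from -7.33 to -4.36, Etnk2 from -7.02 to -3.48 and Wnt10a from -6.40 to -3.54. Rasa3 itself did not pass (log2 -0.07, SE 0.157, adjusted p = 0.816, 7587 ± 774 against 7959 ± 228).

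Heme synthesis and red cell lists were higher in whole bone marrow in crisis at the preset correlation. With an estimated correlation none of the lists below passed (adjusted p of at least 0.413). Of 14 heme synthesis genes, 4 rose over all genes and 9 when adjusted over the list alone (median log2 0.98, adjusted p = 6.11e-06). Among them were Alas2, the enzyme that starts the pathway (1.01, SE 0.229, adjusted p = 0.0314), and Cpox (1.49, SE 0.383, adjusted p = 0.0421). Of 28 red cell membrane and late erythroid genes, 6 rose over all genes and 18 over the list alone (median 0.96, adjusted p = 1.54e-10), with Epb41 (1.26) as an example. The erythropoietin and STAT5 list (15 genes, 6 up and 1 down; 9 and 1 over the list alone, median 0.85, adjusted p = 6.46e-05) included Socs3 (3.05, SE 0.391) and Pim1 (2.19, SE 0.374), while the kinase gene Pim2 fell by 0.99. Tfrc, the receptor that takes up transferrin iron, rose by 2.01 (SE 0.385, adjusted p = 0.0262), 1 of 2 rising genes of the 14 for iron handling (4 over the list alone, median 0.48, adjusted p = 0.00152). Among 14 erythroid transcription factors Nfe2 rose by 0.98 (6 up and 1 down over the list alone, median 0.54, adjusted p = 0.00801). None of 4 globin genes passed over all genes and 3 did over the list alone (median 0.87, adjusted p = 0.0548). The oxidative stress defence list was higher as well (3 of 18 up, 9 over the list alone, median 0.48, adjusted p = 2.68e-05, Cat 0.66, Srxn1 1.79). So was the p53 response list, with few genes passing (3 up and 1 down of 18, the same over the list alone, median 0.32, adjusted p = 0.010), with the cell cycle inhibitor Cdkn1a at 1.87 (SE 0.265).

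The B cell and megakaryocyte lists moved the other way in whole bone marrow. With an estimated correlation, adjusted p was 0.413 to 0.595 for every list named as passing here. Of 16 B cell genes 6 fell, 14 over the list alone (median -3.33, adjusted p = 7.32e-10), such as the co-receptor gene Cd22 (-1.80, SE 0.458). Of 25 megakaryocyte and platelet genes 2 fell, Mmrn1 (-2.27, SE 0.433) and the integrin gene Itgb3 (-0.95, SE 0.193), and 1 up and 5 down passed over the list alone (median -0.91, adjusted p = 3.82e-04). The mast cell, basophil and eosinophil list was lower (13 genes, 1 down, 2 over the list alone, median -0.47, adjusted p = 0.010; Prg3 -1.22). Monocyte and macrophage genes were higher (4 of 19 up, 7 over the list alone, median 0.72, adjusted p = 6.46e-05), including Adgre1, the F4/80 antigen (0.56, SE 0.132). Mitochondrial transcripts made up 5.09 to 6.84% of crisis libraries and 2.79 to 4.04% of WT libraries, and adult globins 10.9 to 14.6% and 6.06 to 11.6%.

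In total limma called 1384 of 16144 genes in whole bone marrow, 566 up and 818 down, of which 274 and 479 by at least 2-fold. The crisis and WT libraries do not overlap for 1383 of these genes and for 32.9% of all tested genes, where chance gives 10%. The number of genes called is sensitive to leaving out 1 library. Without crisis replicate 1 limma called 2180 genes. Without any 1 of the other 5 crisis and WT libraries (crisis replicates 2 and 3, WT replicates 1, 2 and 3) it called 0, with 2957 to 3688 at an unadjusted p under 0.05. The log2 change of Erfe stayed between 5.44 and 6.67 over its 16 settings, with an adjusted p of 8.28e-06 to 0.128. The deposited values without rescaling gave 244 genes.

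**Figure D1:**
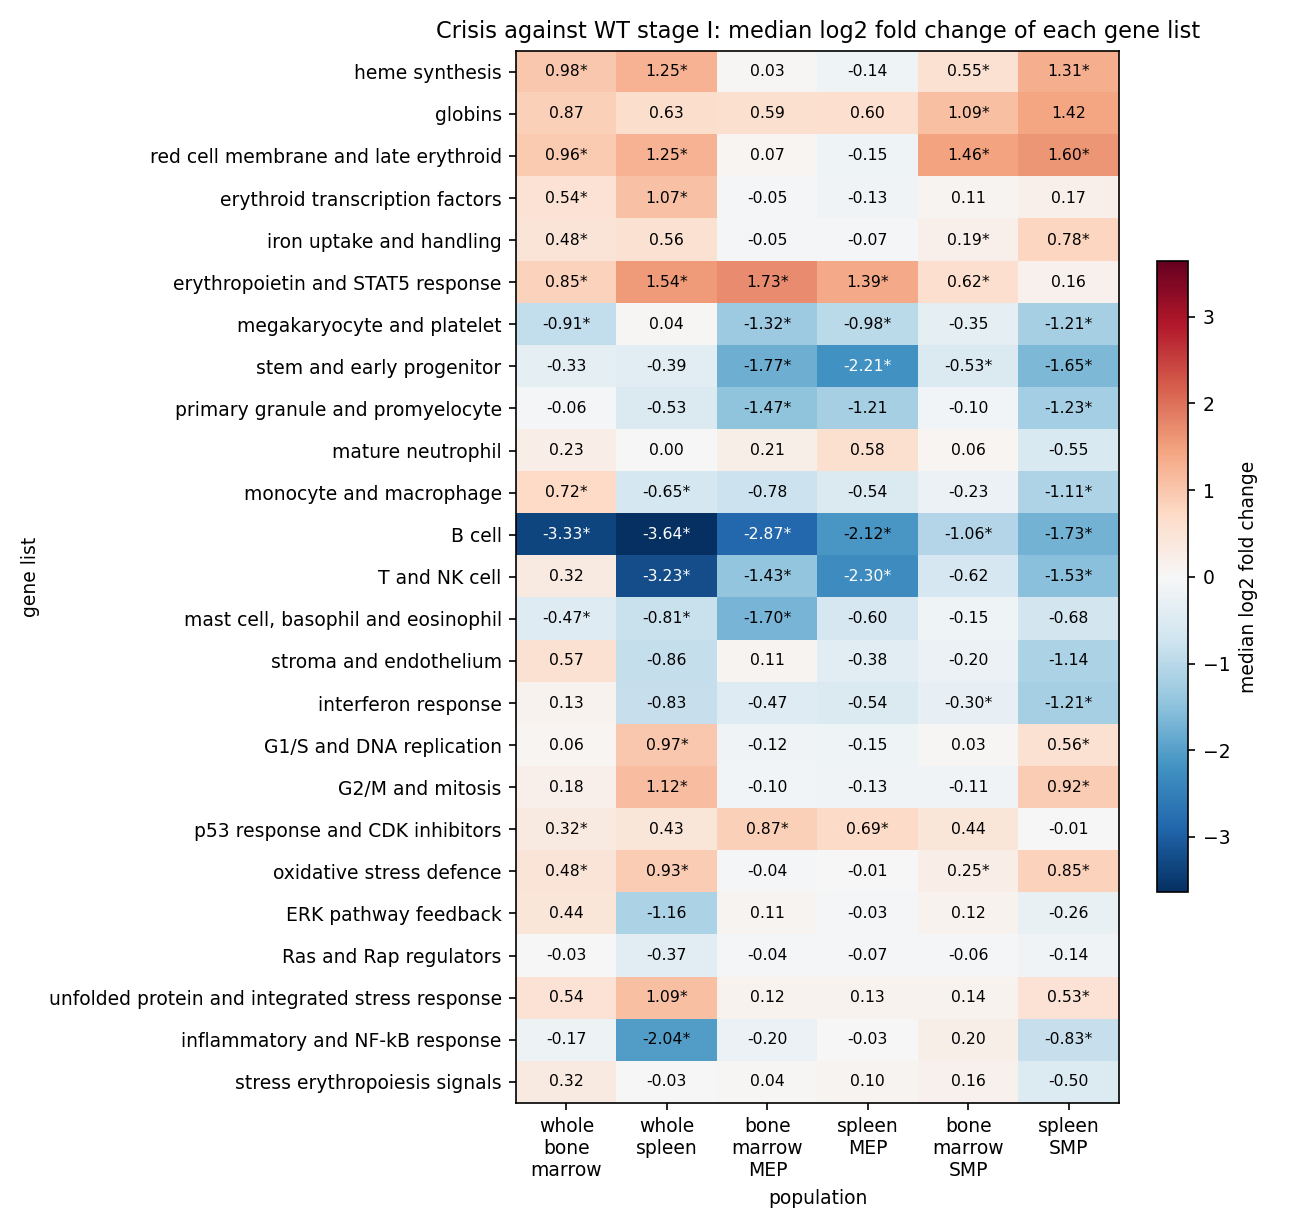
Median log2 change in crisis against WT of the members of 25 gene lists in 6 populations. Asterisks mark an adjusted p under 0.05 with a preset correlation; no list passes with an estimated correlation.

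In whole spleen in crisis, Erfe was 118-fold higher (log2 6.89, SE 1.62, adjusted p = 0.028, 33453 ± 11613 against 286 ± 128, n = 3 and 3). Podxl, a sialomucin of erythroid cells under erythropoietin, was 140-fold higher (log2 7.13, SE 1.48, adjusted p = 0.0233, 8613 ± 3263 against 64.5 ± 32.5). Klre1, a receptor of natural killer cells, is listed at 0 in the 3 crisis libraries against 82.4 ± 20.5 (adjusted p = 0.0224). Rasa3 fell by 2.18 (SE 0.524, adjusted p = 0.0296, 2985 ± 718 against 13264 ± 386). Ankrd36 is listed at 0 in WT and reached 912 ± 1061 (adjusted p = 0.0224). Other genes named by rule were C2cd4a (6.75, 0.0224), Rapgefl1 (-6.03, 0.0279), the mast cell protease Mcpt1 (-5.64, 0.0225), Lynx1 (-5.48, 0.0238) and the growth hormone gene Gh (-5.36, 0.0319). The size of the falls among these is uncertain, as their crisis libraries run up from 0 (Rapgefl1 0 to 135). Over the settings Mcpt1 ran from -6.68 to -4.07, Lynx1 from -6.69 to -4.02 and Gh from -7.03 to -3.80.

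The fall of lymphocyte genes in whole spleen covered nearly whole lists, although as lists none passed with an estimated correlation (smallest adjusted p 0.636). Of 18 T and NK cell genes 17 fell, also over the list alone (median -3.23, adjusted p = 3.81e-09), such as Cd3g of the T cell receptor complex (-3.48, SE 0.667) and Gzma (-3.78, SE 0.678). Of 16 B cell genes 13 fell, and all 16 over the list alone (median -3.64, adjusted p = 3.81e-09), such as Cd79b (-3.53, SE 0.598). Inflammatory and NF-kB response genes fell in 9 of 14 (12 over the list alone, median -2.04, adjusted p = 2.01e-05), including Nfkb2 (-2.31) and the cytokine gene Il1b (-2.52). Monocyte and macrophage genes fell less (4 of 20, also over the list alone, median -0.65, adjusted p = 0.0131; Lyz2 -1.09, Siglec1 -1.85). So did the mast cell list (3 of 13, also over the list alone, median -0.81, adjusted p = 0.0303; Cpa3 -2.08). The regulators of Ras and Rap gave 5 falling genes of 20 and 6 over the list alone (median -0.37, adjusted p = 0.183). Among them were Rasgrp2, which activates Rap1 (-2.67, SE 0.451), and Rasal3 (-2.91, SE 0.507).

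Erythroid and proliferation lists were higher in whole spleen as lists, while few members passed alone in the fit of all groups. That fit gives each gene 1 spread, shared with remission. Remission pairs with replicate 1 (mouse 2726) varied by 42.3 and 39 times sampling noise, the other remission pair by 5.02. Crisis and young WT pairs varied by 4.45 to 11.2 times. With crisis and young WT libraries alone, limma called 3595 rising genes instead of 451. List members passing there are not given here, so few calls do not show that members did not rise. Adjusted p with an estimated correlation was 0.636 or 0.675 for each list passing in whole spleen. None of 14 heme synthesis genes passed over all genes or over the list (median 1.25, adjusted p = 0.00489; Cpox 2.06, SE 0.904), and none of 28 red cell genes (median 1.25, adjusted p = 2.52e-04; Rhag 2.04, SE 0.926). The same held for 14 erythroid transcription factors (median 1.07, adjusted p = 0.0495), 20 G1/S and DNA replication genes (median 0.97, adjusted p = 0.00232; Tyms 1.09) and 20 G2/M genes (median 1.12, adjusted p = 0.00225; Ccnb1 1.54). Erythropoietin and STAT5 genes did pass alone (7 up and 1 down of 15; 7 and 2 over the list alone, median 1.54, adjusted p = 0.00489), with Cish at 5.59 (SE 0.666), Socs3 at 2.11 and the cytokine gene Osm at 2.23. Oxidative stress defence had 1 rising gene of 18, Txnrd1 (1.33), and 0 over the list alone (median 0.93, adjusted p = 9.88e-05). The unfolded protein list had 1 falling gene, Pdia4 (-1.46, list median 1.09, adjusted p = 0.0446).

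In total limma called 2447 of 16150 genes in whole spleen, 451 up and 1996 down (299 and 1906 by at least 2-fold). None of these genes overlaps between crisis and WT, and 58.1% of all tested genes do not, where chance gives 10%. Without crisis replicate 1 limma called 238 genes and without any 1 of the other 5 libraries 0 (3929 to 4918 at an unadjusted p under 0.05). With single-step libraries as a covariate it called 0 (4652), and without mice 2726 and 27265 it called 7729, of which 2429 are shared. The excess of falling genes depends on the setting: there were 3707 up and 4022 down without these mice, 3595 and 3867 with crisis and young WT alone, and 3281 and 3670 with age as a covariate.

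**Figure D2:**
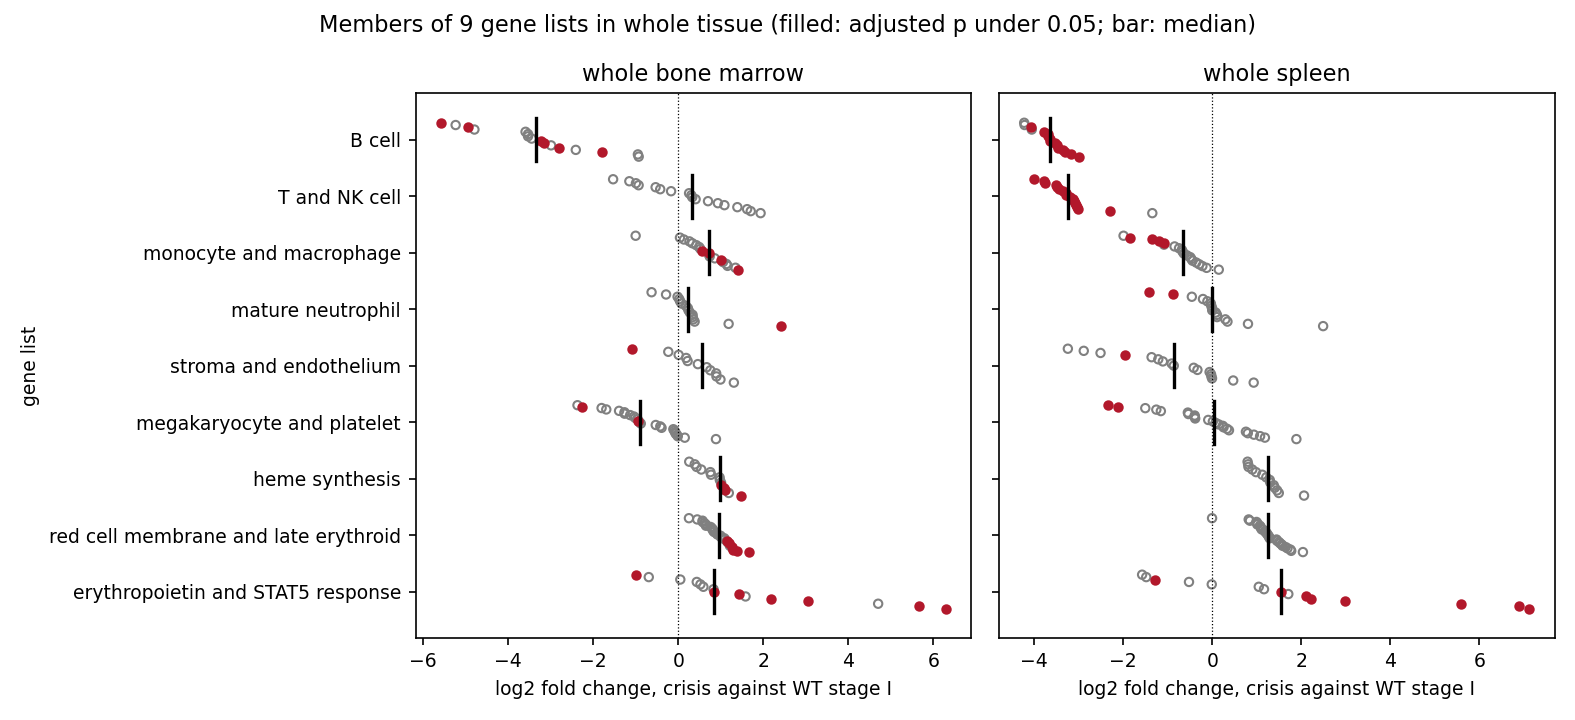
Log2 change in crisis against WT of each measured member of 9 gene lists in whole bone marrow and whole spleen (n = 3 and 3).

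In bone marrow MEP in crisis, 1 gene passed: Slc16a3, a lactate exporter of glycolytic cells, was 8.96-fold higher (log2 3.16, SE 0.294, adjusted p = 0.00876, 1354 ± 357 against 148 ± 22.1, n = 3 and 3). Rasa3 stood at 1878 ± 242 against 2662 ± 851 (log2 -0.47, SE 0.330, adjusted p = 0.533), and Erfe at 4079 ± 2768 against 176 ± 34.4 (log2 4.32, SE 1.11, adjusted p = 0.272). The erythropoietin and STAT5 list was higher (14 genes, 0 over all genes, 6 up over the list alone, median 1.73, adjusted p = 1.68e-05). So was the p53 list (18 genes, 0 over all genes, 10 up and 1 down over the list alone, median 0.87, adjusted p = 3.51e-05; Zmat3 2.35, Ccng1 0.79). The stem and early progenitor list was lower (21 genes, 1 over the list alone, median -1.77, adjusted p = 8.71e-05; Ifitm1 -3.08, SE 0.627). The same held for the megakaryocyte (-1.32, 0.00181), primary granule (-1.47, 0.00679), B cell (-2.87, 3.51e-05), T and NK cell (-1.43, 3.51e-05) and mast cell lists (-1.70, 0.00975). With an estimated correlation, adjusted p was 0.651 or 0.778 for these. Limma tested 14439 genes (1839 at an unadjusted p under 0.05). Without crisis replicate 1 it called 423 genes, Slc16a3 among them, and without any 1 of the other 5 libraries 0 (937 to 1516).

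In spleen MEP in crisis, Hif3a, a hypoxia-inducible factor subunit, rose by 1.77 (SE 0.183, adjusted p = 0.0282, 3784 ± 842 against 1088 ± 16.9, n = 3 and 3), and Homer2 rose by 5.12 (SE 0.67, adjusted p = 0.049, 2167 ± 1401 against 58.4 ± 46.1). The septin gene Sept1 rose 2.83-fold (adjusted p = 0.049), and Slc22a3, a transporter of organic cations, fell by 2.70 (SE 0.338, adjusted p = 0.049). The last of the 5 called genes, 0610040J01Rik (4.89, SE 0.636, adjusted p = 0.049), lies outside the naming rule and was chosen after its values were seen. Rasa3 was at 1472 ± 131 against 1484 ± 490 (log2 0.03, SE 0.203, adjusted p = 0.939). The stem list was lower (21 genes; 2 up and 13 down over the list alone, median -2.21, adjusted p = 1.44e-05; Ifitm1 -3.95, Angpt1 -2.21). So were the T and NK (11 of 15 over the list alone, -2.30, 1.44e-06), B cell (0 of 16 over the list alone, -2.12, 2.89e-04) and megakaryocyte lists (4 of 15; -0.98, 0.0226). The erythropoietin list (14 genes; 7 up and 1 down over the list alone, median 1.39, adjusted p = 2.81e-04; Socs3 3.25) and the p53 list (17 genes, 0 over the list alone, 0.69, 0.0377) were higher. The smallest adjusted p with an estimated correlation was 0.65. Limma called 5 of 13676 genes. Without rescaling there were 304, with all WT mice as the control 193, and with single-step libraries as a covariate 0. These counts are from limma as well. Without crisis replicate 1 it called 197 and without crisis replicate 2 it called 2. Without crisis replicate 3 or any 1 of the 3 WT libraries it called 0 (1802 to 2371 at an unadjusted p under 0.05).

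In bone marrow SMP in crisis, metallothionein genes, which bind zinc, rose: Mt2 by 7.34 (SE 0.947, adjusted p = 0.012, 3560 ± 3447 against 7.01 to 43.8 in the WT libraries, n = 3 and 3) and Mt1 by 4.70 (SE 0.732, adjusted p = 0.0185, 3207 ± 2565 against 104 ± 44.7). Trnp1, a nuclear regulator of the cell cycle, rose by 7.55 (SE 1.597, adjusted p = 0.0271, 2997 ± 4895 against 2.46 ± 2.14, most of it from crisis replicate 3 at 8647), with the receptor gene Mchr1 (6.30, 0.0266) and Homer2 (4.65, 0.026). The matrix genes Col1a1 (-2.71, SE 0.606, adjusted p = 0.0278) and Postn (-2.29, SE 0.421, adjusted p = 0.0217, 542 ± 198 against 2547 ± 126) fell, with Edaradd (-2.31, 0.0208), Rhbdl3 (-2.13, 0.0257) and Gria2 (-2.06, 0.0265). Over 16 settings Col1a1 ran from -3.425 to -0.995, with an adjusted p of up to 0.619 in limma. Its WT libraries held 93.7 to 534. Rasa3 fell by 0.38 (SE 0.089, adjusted p = 0.0316, 8132 ± 1059 against 10511 ± 330.4).

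In bone marrow SMP the red cell and heme synthesis lists were higher and the stem list lower at the preset correlation, and no list passed with an estimated one (adjusted p = 0.344 to 0.634). Of 28 red cell genes 16 rose, and 25 up and 1 down passed over the list alone (median 1.46, adjusted p = 1.12e-14), such as the membrane skeleton gene Add2 (3.86, SE 0.646). Of 14 heme synthesis genes 10 rose, also over the list alone (median 0.55, adjusted p = 1.3e-08; Cpox 1.98, SE 0.315). Of 4 globin genes 2 rose, 4 over the list alone (median 1.09, adjusted p = 0.00126; Hbb-bs 1.201, SE 0.251). The erythroid master regulators Gata1 (0.92, SE 0.181) and Klf1 (1.45, SE 0.313) rose among 14 erythroid transcription factors (3 up and 2 down, 4 and 3 over the list alone, median 0.11, adjusted p = 0.272). Foxo3 fell by 0.55. Tfrc rose by 2.06 (iron list: 4 of 14 up, 6 up and 2 down over the list alone, median 0.19, adjusted p = 0.0395), and Epor, the erythropoietin receptor, by 1.74 (5 of 14 up, 6 over the list alone, median 0.62, adjusted p = 0.0017). Oxidative stress defence genes rose (4 of 18, 5 over the list alone, median 0.25, adjusted p = 0.00466; Prdx2 0.47). Of 22 stem and early progenitor genes 6 fell, 10 over the list alone (median -0.53, adjusted p = 9.12e-06): the endothelial and stem cell receptor Tie1 (-1.21, SE 0.189), Cd34 (-0.74, SE 0.135) and Meis1 (-0.64, SE 0.124). Interferon response genes were lower (1 up and 2 down of 23, 1 and 4 over the list alone, median -0.30, adjusted p = 0.00177; Gbp2 -0.97, Rsad2 1.13). So was the B cell list (0 of 16 over all genes, -1.06, 0.013).

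In total limma called 1148 of 15261 genes in bone marrow SMP, 570 up and 578 down (225 and 105 by at least 2-fold). Groups do not overlap for 1146 of them and for 30.2% of all tested genes, where chance gives 10%. The count was 3167 without crisis replicate 1, 237 without crisis replicate 2, 242 without crisis replicate 3, 18 without WT replicate 1, 234 without WT replicate 2 and 0 without WT replicate 3 (2842 at an unadjusted p under 0.05). Deposited values without rescaling gave 281 genes, 235 up and 46 down, so the balance of directions depends on the scaling. Age as a covariate gave 225.

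In spleen SMP in crisis, Mt2 rose by 5.48 (SE 0.801, adjusted p = 0.0217, 15000 ± 10308 against 281 ± 148, n = 3 and 3), Homer2 by 6.41 (SE 1.002, adjusted p = 0.0217, 2316 ± 1933 against 14.1 ± 4.19) and Erfe by 4.76 (SE 0.878, adjusted p = 0.0217, 2631 ± 2984 against 60.4 ± 29.3). The other highest were C2cd4a (6.64, 0.0217) and Trnp1 (5.55, 0.0361), which rests on 1 mouse (38.9, 416.6 and 20108 in the crisis libraries, log2 from 3.13 to 7.61 over the settings, adjusted p up to 0.162). The lowest were Fndc10 (-5.16, 0.0239), Fbxl13 (-4.61, 0.0251), the glycoprotein hormone gene Stc1 (-4.41, 0.0264), the guidance receptor Robo1 (-4.05, 0.0298) and Chst1 (-4.05, 0.0232). The size of these falls is uncertain, as the crisis libraries differ widely (Fndc10 0.114 to 78.1). Over the settings Fndc10 ran from -7.13 to -2.59, Fbxl13 from -6.374 to -2.835 and Chst1 from -5.022 to -2.825. Rasa3 fell by 0.95 (SE 0.267, adjusted p = 0.0286, 6314 ± 1976 against 11768 ± 889).

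In spleen SMP no list passed with an estimated correlation (smallest adjusted p 0.448), and the list values here are at the preset one. Of 28 red cell genes 22 rose, 26 over the list alone (median 1.598, adjusted p = 2.3e-09), such as the membrane skeleton gene Ank1 (2.09, SE 0.436). Of 14 heme synthesis genes 11 rose, 14 over the list alone (median 1.31, adjusted p = 2.02e-06; Fech 1.83, SE 0.354). Tfrc rose by 3.09 (SE 0.374), 1 of 7 rising and 1 falling genes of 14 for iron handling (9 and 2 over the list alone, median 0.78, adjusted p = 0.0112). Of 20 G2/M genes 16 rose, also over the list alone (median 0.92, adjusted p = 1.35e-06), among them the mitotic kinases Aurkb (0.93, SE 0.187) and Cdk1 (1.09, SE 0.260). Of 20 G1/S genes 8 rose, 10 over the list alone (median 0.56, adjusted p = 4.82e-05; Rrm2 1.53). Oxidative stress defence (12 of 18 up, 13 over the list alone, median 0.85, adjusted p = 2.33e-05; Prdx2 1.45) and the unfolded protein and integrated stress response (6 of 17 up, 8 up and 1 down over the list alone, median 0.53, adjusted p = 0.00399; Asns 2.93) rose as well. Of 23 stem and early progenitor genes 18 fell and 1 rose, also over the list alone (median -1.65, adjusted p = 1.35e-06), including Fgd5 (-2.52, SE 0.405), Mycn (-1.94, SE 0.314) and Tie1 (-2.44, SE 0.430). Falls of 5 of 10 primary granule genes (6 over the list alone, median -1.23, adjusted p = 0.0045; Cebpa -1.52), 6 of 23 megakaryocyte genes (also over the list alone, -1.21, 4.06e-04), 8 of 17 T and NK cell genes (9 over the list alone, -1.53, 6.89e-04; Tcf7 -2.96) and 7 of 15 NF-kB genes (also over the list alone, -0.83, 0.00453; Icam1 -1.75) accompanied this. The interferon (10 of 24 down; 1 up and 13 down over the list alone, -1.21, 0.00108), macrophage (3 of 16 down, -1.11, 0.00399) and B cell lists (2 of 16 down, 0 over the list alone, -1.73, 0.00272) were also lower.

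In total limma called 4796 of 15461 genes in spleen SMP, 2503 up and 2293 down (908 and 1733 by at least 2-fold). Groups do not overlap for 4716 of them and for 50.3% of all tested genes, where chance gives 10%. The count was 6392 without crisis replicate 1, 1101 without crisis replicate 2, 2532 without crisis replicate 3, 2 without WT replicate 2 and 0 without WT replicate 1 or 3 (5785 and 6256 at an unadjusted p under 0.05). Deposited values without rescaling moved the median of all genes by -0.51 and gave 140 rising and 2164 falling genes, so directions here are relative to the median gene.

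**Figure D3:**
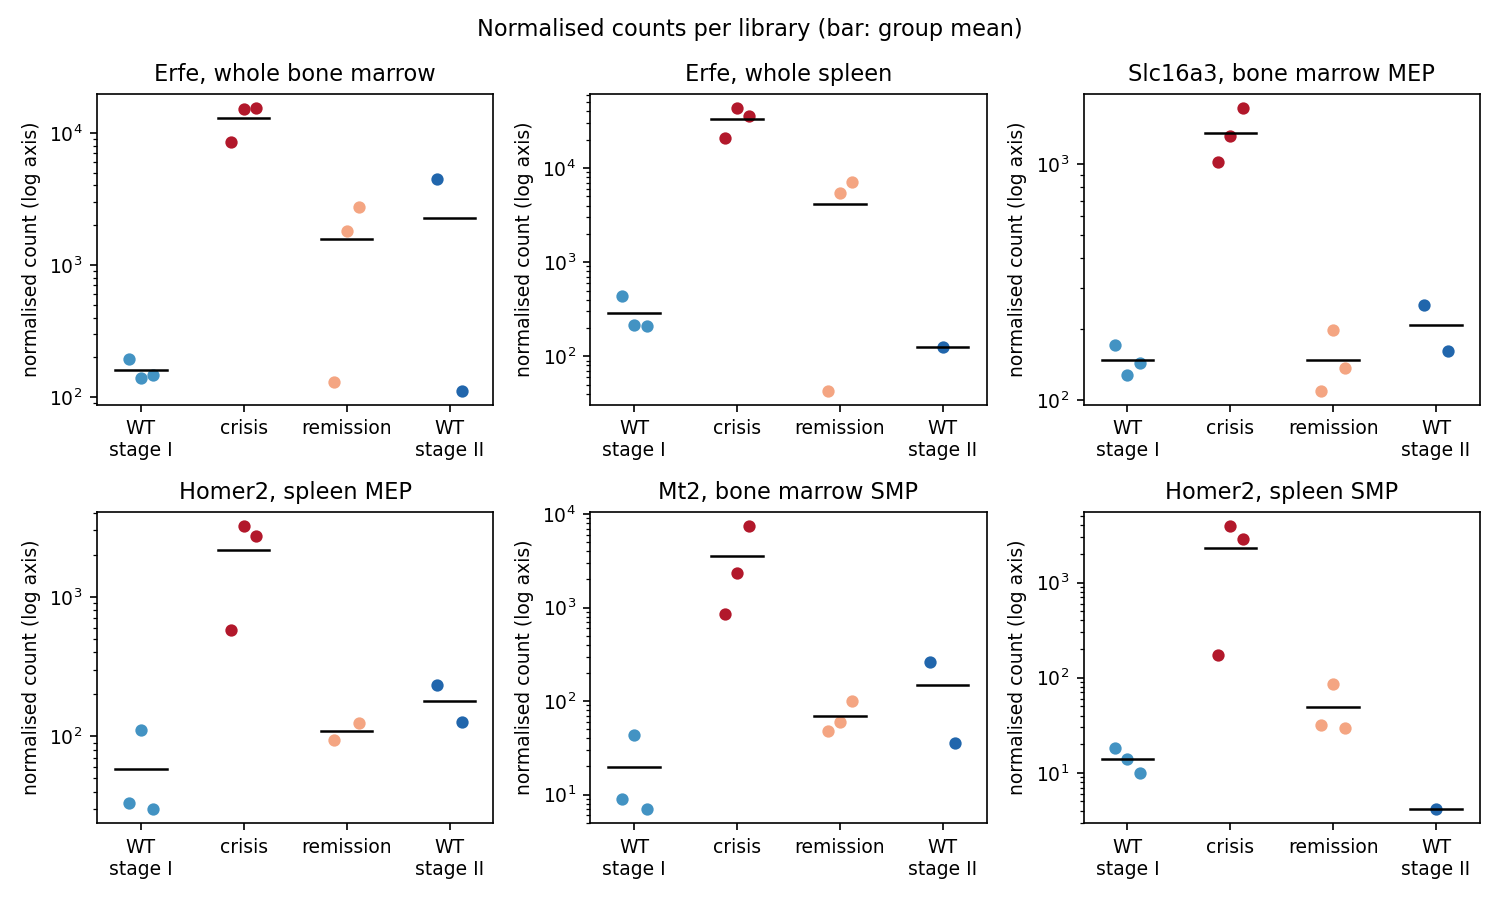
Rescaled normalised counts per library of Erfe in whole bone marrow and whole spleen, Slc16a3 in bone marrow MEP, Homer2 in spleen MEP and spleen SMP, and Mt2 in bone marrow SMP. Each point is 1 mouse.

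The crisis effect was compared between tissues with a test of the difference, spleen minus bone marrow. In whole tissue Rasa3 differed by -2.14 (SE 0.484, adjusted p = 0.0127), with -2.18 in spleen and -0.07 in bone marrow. Whether a change of cell make-up gave this value in whole tissue was not tested. Arpp21, a regulator of calmodulin and cAMP signalling, fell in bone marrow (log2 -1.89, adjusted p = 0.0442) and stood at 1.82 in spleen (adjusted p = 0.0773; difference 3.61, SE 0.695, adjusted p = 0.00607). Nrn1, a neuritin gene, rose in bone marrow (5.50, adjusted p = 0.0262) and stood at -1.41 in spleen (adjusted p = 0.322; difference -6.82, SE 1.28, adjusted p = 0.00556). Limma called 1696 of 16337 genes, 206 with a higher and 1490 with a lower effect in spleen, and between 804 and 1686 when 1 library was left out. Without mice 2726 and 27265 there were 1873 and 2890, so the excess of lower effects depends on the setting. Limma called 464 genes without the animal block, 1030 without the filter on low values and 50 without rescaling. Without bone marrow crisis replicate 2 it called 855, without bone marrow WT replicate 1 it called 855 and without bone marrow WT replicate 2 it called 839. Without spleen crisis replicate 1 it called 808 and without spleen WT replicate 2 it called 804, while 946, 932, 1085, 1179 and 1139 followed without bone marrow crisis replicate 3, spleen WT replicate 3, bone marrow WT replicate 3, bone marrow crisis replicate 1 and spleen crisis replicate 2. In MEP, limma called 0 of 14156 genes (697 at an unadjusted p under 0.05; Rasa3 0.51, SE 0.289, adjusted p = 0.958). In SMP it called 3 of 15399 genes (4757), among them Mir99ahg, the host transcript of a microRNA cluster (-2.48, SE 0.402, adjusted p = 0.0477), and, chosen after its value was seen, Gm17509 (-2.87, SE 0.453). Rasa3 stood at -0.58 (SE 0.265, adjusted p = 0.148). The SMP count was 0 without the animal block, without the filter on low values, without rescaling and without mice 2726 and 27265. Without spleen crisis replicate 1 the SMP count was 4033, without spleen crisis replicate 3 it was 1491, without bone marrow crisis replicate 1 it was 4, and without any 1 of the other 9 libraries it was 0 (2939 to 4571).

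In whole bone marrow, no single gene passed between remission and crisis. Igll1 stood at 3704 ± 633 in remission against 581 ± 965 in crisis (log2 5.22, adjusted p = 0.169, n = 3 and 3), and Socs3 at 334 ± 97.4 against 1563 ± 615 (log2 -2.18, adjusted p = 0.125). Rasa3 was at 7767 ± 1760 against 7587 ± 774 (log2 0.01, SE 0.157, adjusted p = 0.976). The B cell list was higher (16 genes, 13 up over the list alone, median 2.62, adjusted p = 6.67e-10, and 0.392 with an estimated correlation). So was the mast cell list (10 over the list alone, 0.79, 1.97e-06). The erythropoietin (1 up and 6 down over the list alone, -0.64, 8.78e-05), red cell (-0.52, 8e-07), heme synthesis (-0.52, 0.00185) and macrophage lists (-0.43, 0.0156) were lower. For all these lists against crisis, adjusted p with an estimated correlation was 0.357 or higher. Between young WT (0) and crisis (1), the remission library of mouse 2726 lies at 0.057 and the others at 0.48 and 0.533. List values against crisis without mouse 2726 are not given here, so these changes may rest on it in part. Limma called 0 genes (2538 at an unadjusted p under 0.05) and 1056 without crisis replicate 1. Against WT of the same stage it called 0 as well (186; n = 3 and 2), with Rasa3 at a log2 of -0.003 (SE 0.176, adjusted p = 1). Primary granule (-0.35, 1.11e-07) and neutrophil lists (-0.25, 3.41e-04) were lower and stroma (0.76, 0.0187) and B cell lists (0.62, 0.0339) higher, with 0.997 as the smallest adjusted p with an estimated correlation. Without mice 2726 and 27265 limma called 0 genes against crisis (2013) and 1 against WT (n = 2 and 1). The stroma (0.35, 0.0934) and B cell lists (-0.205, 0.11) then no longer passed against WT, while red cell (1.06, 1.07e-29) and heme synthesis lists (0.985, 6.71e-17) did, with 0.171 as the smallest adjusted p with an estimated correlation.

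In whole spleen in remission, Cish stood at a log2 change of -3.62 against crisis (adjusted p = 0.133; n = 3 and 3). Rasa3 was at 10335 ± 9582 (log2 1.44 against crisis, SE 0.524, adjusted p = 0.188 in limma). Against the single WT library of 16149 its log2 change was -1.03 (SE 0.741). Its 3 remission libraries ran from 4554 to 21396, and the crisis libraries from 2156 to 3407. The highest remission library lies above the WT library, so neither log2 change describes all 3 remission libraries. Against crisis the B cell (16 genes, 13 up over the list alone, median 2.50, adjusted p = 3.43e-09), T and NK cell (17 of 18; 2.29, 3.43e-09) and NF-kB lists (10 of 14; 1.55, 5.52e-06) were higher. The red cell (-1.18, 1.14e-05), heme synthesis (-1.01, 0.00211) and G2/M lists (-1.19, 8.93e-05) were lower. Compared with the single WT library (n = 3 and 1), so without a spread among WT mice, the red cell (1.15, 4.74e-05), heme synthesis (1.09, 3.8e-04) and G2/M lists (1.02) stood higher. The T and NK (-1.36, 1.17e-05) and B cell lists (-1.26) stood lower. The smallest adjusted p with an estimated correlation was 0.557 against crisis and 0.664 against WT. Limma called 0 genes in both contrasts (3250 and 130 at an unadjusted p under 0.05). Without remission replicate 1, which is mouse 2726, it called 521 against crisis (457 up) and 4655 against WT (2675 up, 1980 down). Without crisis replicate 1 it called 5 against crisis. Without the 2 doubtful mice the red cell (0.003), heme synthesis (-0.07) and G2/M lists (-0.05) no longer passed against crisis. Against the single WT library all 14 heme synthesis genes were then higher (median 2.23, adjusted p = 1.68e-10, and 0.281 with an estimated correlation), with 26 of 28 red cell genes (2.38, 2.54e-16). At the same time 17 of 18 T and NK cell genes were lower (-2.17) and 12 of 16 B cell genes (-1.96).

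In bone marrow MEP, Slc16a3 returned from 1354 ± 357 in crisis to 149 ± 45.6 in remission (log2 -3.19, SE 0.294, adjusted p = 0.00817, n = 3 and 3), the only 1 of 14439 genes called (1651 at an unadjusted p under 0.05). Rasa3 was at 2405 ± 867 (log2 0.29 against crisis, SE 0.330, adjusted p = 0.752; -0.51 against WT, SE 0.369, adjusted p = 1). The erythropoietin (0 up and 7 down over the list alone, -1.91, 8.98e-06) and p53 lists (6 down over the list alone, -1.03, 2.46e-05) were lower than in crisis, and the stem (1.57, 3.42e-05) and T and NK lists (1.29, 8.98e-06) higher, with 0.599 as the smallest adjusted p with an estimated correlation. Against WT (n = 3 and 2) limma called 0 genes (201), and the neutrophil list was lower (10 down over the list alone, median -2.41, adjusted p = 2.96e-18, and 0.222 with an estimated correlation; Ltf, lactoferrin, -2.73). Slc16a3 was not called without crisis replicate 2 or 3 or without remission replicate 1 (0 genes, 1091 to 1137 at an unadjusted p under 0.05). The count was 151 without crisis replicate 1, 2 without remission replicate 2 and 4 without remission replicate 3. Without mice 2726 and 27265 it was 0 against crisis and against WT (1196 and 735), and the lists named here still passed at the preset correlation. In spleen MEP limma called 0 genes against crisis (952; n = 2 and 3) and against WT (575; n = 2 and 2). Rasa3 was at 1355 ± 197 (log2 -0.12, SE 0.227, adjusted p = 0.95; -0.30 against WT, SE 0.249, adjusted p = 0.999), and Ifitm1, an interferon-induced stem cell marker, at 3.98 against crisis (adjusted p = 0.352). The stem list was higher than in crisis (3 over the list alone, 1.25, 8.46e-04) and lower than in WT (-1.61, 1.17e-08). Red cell (0.41, 2.99e-09) and G2/M lists (0.35, 2.55e-17) were higher than in WT. The smallest adjusted p with an estimated correlation was 0.929 against crisis and 0.334 against WT. Without crisis replicate 1 limma called 17 genes against crisis, and it called 1 without crisis replicate 2 or remission replicate 1. Against WT it called 1 without WT replicate 1. Without mouse 27265 in the fit it called 3 against crisis, and the red cell list no longer passed against WT (0.16, 0.0778).

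In bone marrow SMP, 190 genes passed between remission and crisis, a call that ends in several settings. Limma called 0 without mice 2726 and 27265 (2522 at an unadjusted p under 0.05) and 0 in the difference of differences (2269), and another split of the same libraries gave 249. The difference of differences takes the change with age from older WT mice 27265 and 2761. These lie at 0.64 and 0.045 between young WT (0) and crisis (1). Age and the place of mouse 27265 thus cannot be told apart in it. Mt2 fell by 5.21 (SE 0.947, adjusted p = 0.036, 69.4 ± 28.0 against 3560 ± 3447, n = 3 and 3) and Homer2 by 4.76 (SE 0.98, adjusted p = 0.0453), with the complement receptor C5ar2 (-2.93, 0.036), Il13ra1 (-2.55, 0.0469) and the zinc transporter Slc30a2 (-2.52, 0.0358). Phldb2, which anchors microtubules, rose by 1.97 (SE 0.318, adjusted p = 0.0272, 124 ± 38.9 against 30.9 ± 9.80), with the growth factor Gdf11 (1.93, 0.0388), Mapk12 (1.83, 0.0487), Padi4 (1.77, 0.036) and Pdzph1 (1.76, 0.0358). Rasa3 was at 10747 ± 166 (log2 0.41, SE 0.089, adjusted p = 0.0505). Of 22 stem genes 4 rose, 11 over the list alone (median 0.57, adjusted p = 8.63e-06), such as Tie1 (1.24) and Cd34 (0.74). Heme synthesis (1 of 14 down, 8 over the list alone, -0.38, 2.41e-04; Cpox -1.59) and red cell lists (0 over all genes, 14 over the list alone, -0.69, 1.35e-07) were lower, with 0.638 as the smallest adjusted p with an estimated correlation. These list values against crisis are not given here without mouse 2726. Of the 190 genes 126 were up and 64 down, and 105 of them had fallen and 60 had risen in crisis. Lists drawn independently would share 4.77 and 2.39 genes, and 20 simulated draws without any change shared 0 at most. Neither comparison shows a shared effect, because both contrasts use the crisis libraries, from which part of the excess may come. Without rescaling limma called 164 genes, 32 up and 132 down, of which 37 are shared, so the balance of directions depends on the scaling. The count was 2716 without crisis replicate 1, 1 without crisis replicate 2, 35 without remission replicate 3, and 0 without crisis replicate 3 or remission replicate 1 or 2 (2626 to 2992 at an unadjusted p under 0.05). Against WT limma called 0 (195; n = 3 and 2; Rasa3 0.01, SE 0.099, adjusted p = 1) and 2 without WT replicate 1. The neutrophil list was lower (-1.34, 3.07e-10, and 0.911 with an estimated correlation), but higher without the 2 doubtful mice (0.35, 0.0136), where limma called 0 genes against WT (206).

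In spleen SMP limma called 0 genes between remission and crisis (3221 at an unadjusted p under 0.05; n = 3 and 3) and 1930 without crisis replicate 1. Rasa3 was at 9732 ± 2795 (log2 0.63, SE 0.267, adjusted p = 0.226; -0.36 against the single WT library, SE 0.378, adjusted p = 0.719). The stem (15 up and 1 down over the list alone, 1.49, 1.6e-09), interferon (13 up over the list alone, 1.35, 9.11e-08) and megakaryocyte lists (0.97, 4.98e-07) were higher. Heme synthesis (9 down over the list alone, -0.83, 2.75e-06) and red cell lists (-0.86, 1.72e-08) were lower than in crisis. Compared with the single WT library (n = 3 and 1), so without a spread among WT mice, the red cell list stood higher (11 over the list alone, 1.27, 9.07e-13), as did heme synthesis (0.83) and globins (1.72). The smallest adjusted p with an estimated correlation was 0.569 against crisis and 0.514 against WT. The 2 genes called against WT, Nlrp6, an inflammasome sensor (3.97, SE 0.457, adjusted p = 0.0345), and Amd-ps3 (6.71, SE 0.392), lie outside the naming rule and were chosen after their values were seen. The count was 1 without remission replicate 1 and 1 without remission replicate 3.

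How far the crisis changes persisted was measured as the median log2 difference between remission and WT, taken in the crisis direction of each called gene. In whole spleen and spleen SMP this rests on 1 WT library each. In whole spleen it was 0.88 (3 libraries from -0.13 to 1.45, SD 0.87) where crisis itself gave 2.04, and 97.3% of the 2447 genes kept the sign of crisis. Without mouse 2726 it was 1.4. In spleen SMP it was 0.56 (0.33 to 0.90, SD 0.30; crisis 1.07; 95.5% of genes). In whole bone marrow it was -0.12 (SD 0.10; crisis 1.08; 29% of genes) and in bone marrow SMP -0.02 (SD 0.05; crisis 0.64; 42.5%). Without mice 2726 and 27265 it was 0.17 in whole bone marrow and 0.12 in bone marrow SMP. Leaving out 1 library at a time it stayed at 0.59 to 1.4 in whole spleen and 0.396 to 0.676 in spleen SMP, and spanned -0.375 to 0.126 in whole bone marrow and -0.147 to 0.105 in bone marrow SMP.

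**Figure D4:**
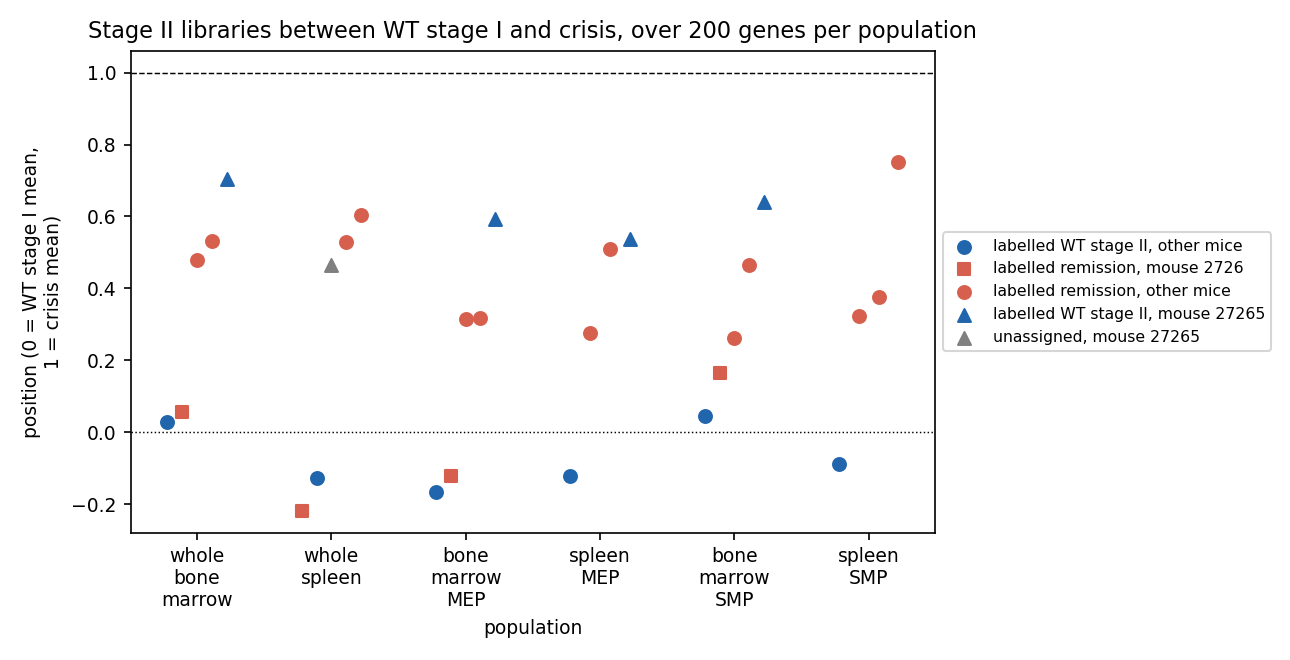
Position of each library of mice aged 32 to 58 days between the means of young WT (0) and crisis (1), over 200 genes per population.

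On GRCm38 with GENCODE release M21, Rasa3 (ENSMUSG00000031453) lies on chromosome 8 at 13566948 to 13677603 on the reverse strand. Erfe (ENSMUSG00000047443) lies on chromosome 1 at 91366430 to 91374217 and Slc16a3 (ENSMUSG00000025161) on chromosome 11 at 120948480 to 120960868, both on the forward strand. Homer2 (ENSMUSG00000025813), which rose in crisis in whole bone marrow, spleen MEP and both SMP populations, lies on chromosome 7 at 81600481 to 81707527 on the reverse strand.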

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

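The tests of cell sources, dilution and sample labels below were chosen after the results were seen, while the tests of the tissue difference and of other splits of the samples were planned. The splits that keep each mouse in 1 state in both tissues were also chosen after the results were seen.

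The crisis effect differed between spleen and bone marrow by a test of the difference itself. In whole tissue 1696 genes passed. Rasa3 differed by -2.14 (SE 0.484, adjusted p = 0.0127 in limma), with -2.18 in spleen and -0.07 in bone marrow. In sorted cells its difference was not called in limma (MEP 0.51, adjusted p = 0.958, and SMP -0.58, adjusted p = 0.148). Whether a change of cell make-up gave the value in whole tissue was not tested. The genes with a higher effect in spleen were Arpp21 (3.61), Prkaa2, a catalytic subunit of AMP-activated kinase (3.43), the myosin gene Myo18b (3.11), Rsph9 (2.89) and Ddc (2.82). Those with a lower effect were the growth factor Igf2 (-6.87), Nipal1 (-6.82), Nrn1 (-6.82), Mcpt1 (-6.53) and Dapl1 (-6.36). Arpp21 and Nrn1 took opposite signs in the 2 tissues, and Rsph9 fell by 2.77 in bone marrow and stood at 0.17 in spleen. Igf2 lies below the filter on low values in spleen, and Mcpt1 and Dapl1 in bone marrow, so the size of these 3 differences is uncertain, and Igf2 was not called in bone marrow (4.44, adjusted p = 0.08). In SMP 3 genes passed, with Mir99ahg at -2.48, and in MEP 0 genes in limma (697 at an unadjusted p under 0.05).

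Splits that keep each mouse in 1 state in both tissues number 10 in whole tissue and in MEP, too few for a share under 0.05. The real count and the highest other were 1696 and 0 in whole tissue (1 of 10 splits gave as many) and 0 and 0 in MEP (10 of 10). In SMP they were 3 and 1 (1 of 28). There the 3 mice with libraries of both tissues are all in crisis and every other split parts them, so no other split is paired as the real one and 28 do not serve for a share. The planned test split the libraries of each tissue on their own, 100 draws. Of these 3 gave as many genes as the real one in whole tissue (highest 2683), 100 in MEP (highest 2) and 6 in SMP (highest 5074, against a real count of 3). These draws give some mice 2 states, and the highest in whole tissue and SMP reverse all 6 spleen labels, so they hold much of the crisis effect itself and do not serve to exclude chance.

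The whole spleen library of mouse 27265, aged 58 days and in no group, holds transcripts that WT spleens nearly lack. Podxl stands at 8035 rescaled normalised counts, where the highest WT library has 87 and the lowest crisis library 5184. Erfe stands at 9327 (highest WT 421, lowest crisis 20230), C2cd4a at 340 (2.24 and 119) and Ankrd36 at 1.87 (0 and 28.4). These genes were named because they are among the highest in whole spleen in crisis.

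The first pattern weighed is the place of the mice 2726 and 27265, both 58 days old, between young WT (0) and crisis (1). The 13 libraries of other remission mice lie at 0.263 to 0.752 (median 0.465), and the 6 of other WT mice of that stage at -0.166 to 0.045. The 4 assigned libraries of 27265, recorded as WT, lie at 0.538 to 0.705 (median 0.617), above every other WT library. Those 6 others come from only 2 mice, both 32 days old, so variation among WT mice, a change with age and a wrong label cannot be told apart. An exchange of the labels of the 2 mice may explain the pattern and stays open. Of their libraries 8 of 8 lie nearer to the mice of the opposite label, but these are 2 mice and the count restates the pattern. For 2726, recorded as remission (median -0.032), a wrong label and a remission mouse back at the WT level cannot be told apart, because its own libraries set no bound on how far a remission can go.

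The second pattern is the rise of heme and red cell genes in SMP in crisis. If late erythroid cells had passed the SMP gate, they would bring their globins. The 26 called heme and red cell genes of bone marrow SMP need a median of 8.46% of crisis whole bone marrow RNA (quartiles 4.82 to 19.2%), while the 4 adult globins allow 0.651 to 0.817%. In spleen SMP the 33 called genes need 11.3% (5.29 to 28.4%) and the globins allow 1.46 to 1.93%. In both tissues the called genes thus need a larger share of whole tissue than the globins allow. The called genes were chosen by their rise in these same libraries, and whole tissue stood in for late erythroid cells. The globins therefore do not decide on late erythroid cells as a source. Other genes high in the whole tissue need a median of 1.6% in bone marrow (340 genes), and 6.33% in spleen (285 genes, quartiles 1.15 to 18%), and the spleen value goes with a whole tissue source. The profile of MEP matches the called genes in amount, which could be MEP inside the gate or SMP moving towards MEP: 147 other MEP genes need 13.9% of MEP RNA in bone marrow and the called genes 12.1%, and in spleen 94 other genes need 41% and the called genes 43.4%. The globins do not follow MEP. They need 23.3 to 36.6% of MEP RNA in bone marrow and 133 to 431% in spleen, where MEP alone cannot supply them. Which of these holds, or a mixture of sources, was not tested, and CD34 and CD16/32 staining in the sort is meant to keep MEP out.

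The third pattern is the fall of B, T and NK cell genes in whole spleen in crisis, a median of -3.45 over 34 genes (quartiles -3.69 to -3.14). Dilution of every resident cell type by expanding erythroid cells would lower all of them alike, and macrophage genes stand at -0.65 (20 genes), stroma and endothelium at -0.86 (17 genes) and neutrophil genes at -0.003 (16 genes), which argues against even dilution. Globin transcripts took 19.5% of crisis and 16.8% of WT libraries, which changes the remaining share by a log2 of -0.048. Rescaling by the median ratio takes such a shift out of the log2 changes beforehand, so this share does not test the fall. With single-step libraries as a covariate the median was -3.45 (-3.448, median SE 0.816, before 0.682), and 0 of 34 genes passed instead of 30 (smallest adjusted p 0.0752, before 0.0224). The median SE grew. In this fit only young WT replicate 1 (mouse 2658) and the single older WT library are single-step. The older WT library is alone in its group, so the covariate rests on mouse 2658. It amounts to leaving that library out, which also gave 0 called genes in limma. Single-step libraries as the whole cause are argued against, as the median stayed over 2 of its SE from 0. The 2 young WT and 3 crisis libraries that then carry the comparison are not of this kind. With the covariate 246 of 16150 genes moved by more than their SE. This reflects mouse 2658 against the other young WT mice and shows nothing particular to single-step libraries. A loss of lymphocytes in crisis stays open, as do age and litter, which were not tested.

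Other splits of the 6 crisis and WT libraries number 10 in each population, too few for a share under 0.05. The real count and the highest other were 1384 and 0 in whole bone marrow (1 of 10 splits gave as many), 2447 and 0 in whole spleen (1 of 10), 1 and 1 in bone marrow MEP (2 of 10), 5 and 1 in spleen MEP (1 of 10), 1148 and 1 in bone marrow SMP (1 of 10) and 4796 and 1 in spleen SMP (1 of 10). Between remission and crisis they were 0 and 3 in whole bone marrow (10 of 10), 0 and 1 in whole spleen (10 of 10), 1 and 119 in bone marrow MEP (3 of 10), 190 and 249 in bone marrow SMP (2 of 10), and 0 and 1931 in spleen SMP (10 of 10). The counts of 119 and 1931, many times the real ones, point to a structure of the samples. The split with 119 genes groups crisis replicate 1 with remission replicates 1 and 2. Those with 249 and 1931 group crisis replicate 1 with remission replicates 1 and 3. Without crisis replicate 1, mouse 2608, limma called 151, 2716 and 1930 genes in these populations, the highest counts with 1 library left out. Why this mouse stands apart from the other crisis mice was not tested. No group holds 4 to 10 libraries, so single libraries were not tested as extremes.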

How the results depend on the processing

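The settings without rescaling, with single-step libraries as a covariate, with crisis and young WT libraries alone, without mice 2726 and 27265, and without the libraries of doubtful animal were chosen after the results were seen. The values of named genes, and of gene lists passing in crisis against WT, were followed under the alternatives. Of these 3375 kept direction and side of the threshold and 2035 kept direction but no longer passed. Another 6 newly passed and 16 changed sign, all of the last Rasa3 where it is not called. Lists of the remission contrasts are not in these counts, and some of them changed sign without mice 2726 and 27265. TMM factors left 329 of 331 named genes as they were, the regularised log2 values 320 of 331 and a pseudocount of 5 344 of 345. Leaving out 1 library left 658 of 2142 such values as they were, and 1472 no longer passed. Genes of low counts are what depth limits, and without the filter on them 47 of 345 named genes no longer passed. Apart from the single-step covariate in whole spleen, why counts moved was not tested. Leaving out mice leaves fewer of them, but this does not account for counts that rose. Without mice 2726 and 27265 the count went from 2447 to 7729 in whole spleen in crisis. In bone marrow SMP between remission and crisis it went from 190 to 0. DESeq2 and a quasi-likelihood test on whole reads were not run, since whole reads could not be recovered, and the age and covariate fits have no value where they could not be fitted. Counts of 0 below are from limma.

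Without rescaling, crisis against WT gave 244 genes in whole bone marrow, 2 in bone marrow MEP, 304 in spleen MEP, 281 in bone marrow SMP and 2304 in spleen SMP. Remission against crisis gave 12 in whole bone marrow, 3 in whole spleen, 2 in bone marrow MEP and 23 in spleen MEP, and remission against WT 1 in spleen MEP, 3 in bone marrow SMP and 4 in spleen SMP. The tissue difference gave 50 in whole tissue and 0 in SMP (3256 at an unadjusted p under 0.05). The median gene moved by -0.51 in spleen SMP crisis and by 0.50 in whole spleen remission against WT. Rasa3 took -0.12 in whole bone marrow remission against crisis and -0.099 in bone marrow SMP remission against WT.

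With all WT mice as the control there were 593 genes in whole bone marrow, 5045 in whole spleen, 3 in bone marrow MEP, 193 in spleen MEP (Rasa3 -0.051) and 1 in spleen SMP remission against WT, and the median of crisis genes in remission was 0.127 in whole bone marrow and 0.065 in bone marrow SMP. With single-step libraries as a covariate there were 0 in whole spleen (4652), 3 in bone marrow MEP, 2 in its remission against crisis, 0 in spleen MEP (1100 at an unadjusted p under 0.05, Rasa3 -0.21), 588 in bone marrow SMP remission against crisis, and Rasa3 at 0.092 in whole bone marrow remission against WT. Age as a covariate gave 6951, 45, 24 and 225 in whole spleen, bone marrow MEP, spleen MEP and bone marrow SMP, and crisis and young WT alone 7462, 28, 159 and 360.

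Without mice 2726 and 27265, crisis against WT gave 7729 in whole spleen, 5 in bone marrow MEP and 172 in spleen MEP. Remission against crisis gave 521 in whole spleen, 0 in bone marrow MEP (1196), 3 in spleen MEP and 0 in bone marrow SMP (2522 at an unadjusted p under 0.05). Remission against WT gave 1 in whole bone marrow, 4655 in whole spleen and 1 in spleen MEP. The tissue difference gave 4763 in whole tissue and 0 in SMP (4357), the median of crisis genes in remission 0.17 in whole bone marrow and 0.12 in bone marrow SMP, and Rasa3 -0.15 (-0.146) in whole bone marrow remission against crisis. This setting has no value in spleen SMP, which holds neither mouse. Without the libraries of doubtful animal, bone marrow MEP remission against crisis gave 4 and spleen MEP crisis 0 (1832). The difference of differences gave 0 in bone marrow MEP (827, Rasa3 -0.039), 0 in bone marrow SMP (2269) and 1 in spleen SMP. No filter gave 2 in bone marrow MEP remission against crisis, 5 in spleen SMP remission against WT, and 1030 and 0 (5178) for the whole tissue and SMP differences. In spleen SMP remission against WT, a pseudocount of 5 gave 4 and the regularised log2 values 4. Without an animal block the differences gave 464 in whole tissue and 0 in SMP (4057). Gene lists passing fell from 183 to 0 with an estimated correlation, at adjusted p from 0.222 to 0.997.

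Leaving out 1 library at a time gave, for crisis against WT, remission against crisis and remission against WT, 0 to 2180, 0 to 1056 and 0 to 0 genes in whole bone marrow, 0 to 238, 0 to 521 and 0 to 4655 in whole spleen, 0 to 423, 0 to 151 and 0 to 0 in bone marrow MEP, 0 to 197, 0 to 17 and 0 to 1 in spleen MEP, 0 to 3167, 0 to 2716 and 0 to 2 in bone marrow SMP, and 0 to 6392, 0 to 1930 and 1 to 2 in spleen SMP. The tissue differences gave 804 to 1686, 0 to 0 and 0 to 4033 in whole tissue, MEP and SMP. The median of crisis genes in remission ran from -0.375 to 0.126 in whole bone marrow, 0.59 to 1.4 in whole spleen, -0.147 to 0.105 in bone marrow SMP and 0.396 to 0.676 in spleen SMP. Rasa3 in whole bone marrow ran from -0.132 to 0.009 in crisis (positive without crisis replicate 1), from -0.149 to 0.182 in remission against crisis (negative without remission replicate 1, and -0.069 without crisis replicate 1) and from -0.169 to 0.168 in remission against WT (0.168 without remission replicate 3, 0.045 without WT replicate 2). In spleen MEP it ran from -0.156 to 0.289 in crisis (-0.156, -0.036 and -0.028 without WT replicate 1, crisis replicate 2 and WT replicate 2) and from -0.272 to 0.027 in remission against crisis (0.027 without remission replicate 2).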

Other observations

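The choice of the libraries and of Eif2s3y below was made after the values were seen, while the gene lists were planned.

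Several lists did not pass as lists in crisis but hold genes that did. In whole bone marrow the interferon list (4 up and 1 down of 24, 6 and 3 over the list alone, median 0.13, adjusted p = 0.26 in camera of limma) includes the ubiquitin-like modifier Isg15 (2.03, SE 0.461) and the antiviral enzyme Rsad2 (1.17, SE 0.218). ERK pathway feedback genes gave 1 up and 2 down of 18 there (3 and 3 over the list alone, median 0.44, adjusted p = 0.274), with Ier3 at 1.87 and the phosphatase gene Dusp2 at -2.29. In whole spleen they gave 3 up and 5 down (4 and 7 over the list alone, median -1.16, adjusted p = 0.176), with Egr3 at -3.80 and Ier3 at 3.43. The stress erythropoiesis list gave 1 falling gene of 14 in whole bone marrow, Smad5 (-0.53, median 0.32, adjusted p = 0.274), and 3 up and 3 down of 11 in spleen SMP (3 and 4 over the list alone, median -0.50, adjusted p = 0.413), with the receptor gene Mst1r at 1.61 and Epas1 at -3.39. In whole bone marrow the mature neutrophil list had 1 rising gene of 16, Stfa2l1 (2.42, median 0.23, adjusted p = 0.0854), the primary granule list 0 of 12 (median -0.06, adjusted p = 0.763), the T and NK cell list 0 of 18 (median 0.32, adjusted p = 0.575) and the stroma and endothelium list 1 falling gene of 12, Pecam1 (-1.10, adjusted p of the list 0.575). With an estimated correlation no list passed in any contrast, at adjusted p of 0.222 to 0.997.

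Eif2s3y, a gene of the Y chromosome, was read in each library as deposited normalised counts. In 54 libraries it stands at 1813 to 8456. It is at 139.8 in the whole bone marrow library of mouse 2955. Under the identifier 32dscat it is at 277 in bone marrow SMP, 366 in whole bone marrow, 529.6 in spleen MEP and 763 in whole spleen, and at 2184 in bone marrow MEP. Under m25dwt it is at 3378 in bone marrow MEP, 1984 in bone marrow SMP, 538.5 in spleen MEP and 3378 in whole spleen.

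The unassigned whole spleen library of mouse 27265 lies at 0.464 between young WT (0) and crisis (1).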
